A study of Homo sapiens with 18 samples.

How the data were processed

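The series had 18 samples of the human leukaemia line K562 in 6 groups of 3. Groups were taken from the sample titles. The 3 FLAG-MSI2 iCLIP samples each had a map of crosslinked positions and a list of low-FDR clusters, and 1 table held gene expression of the 3 FLAG-MSI2 RNA-seq samples. The 12 samples of control shRNA and MSI2 shRNA cells (total RNA and polysomal RNA) were not analysed here. The 3 columns of the expression table were matched to the FLAG-MSI2 RNA-seq group, but carry no replicate number. They were named A, B and C in column order, and all columns of values in the table were used.

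In the crosslink maps, the deposited score of a position is a cDNA count whose sign gives the strand, not scaled to library size, with mapping to hg19 and Ensembl release 59, per the file headers. The aligner and the treatment of random barcodes are not given in the sources used here. In the cluster lists, the deposited score is the cDNA count of a cluster. Clusters were called in each library with 100 permutations, a flank of 15 bases and a false discovery rate under 0.05, with regions treated separately and significant positions joined within a neighbourhood of 15 bases, per the file headers. The events of the map summed over a cluster equalled its score in 96.0%, 96.4% and 96.8% of the clusters of libraries 1, 2 and 3. The expression table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library), deposited by the authors as 1 value per gene symbol and library. Per the submitters' processing notes, CASAVA, TopHat and Cufflinks were used with build hg19, and versions and annotation are not given in the sources used here. Per the labels' protocols, RNA-seq libraries were single-end and made with a TruSeq kit. FPKM depends on the length given to each gene, which weighs on short RNAs such as SNORD36A, and on how reads are divided between near-identical genes.

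Library totals of crosslink events were 6521636, 2352989 and 1546901, and shares of events in 1 library have 95% Wilson intervals. iCLIP cDNAs are counted after removal of duplicates only as far as the authors did so, and intervals cover counting error only. The RNA-seq depth is not given by FPKM. Low values of small RNA genes showed steps, and the most common ratio of library A to library B was 1.21 (43 of 223 genes within 0.03 on the log2 scale). It was 0.829 for A to C (37 of 201 genes). Where such genes had the same number of reads in both libraries, these ratios are the inverse of the ratio of depths.

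Events were counted per chromosome and in 10 kb bins on each strand. Bins with at least 10 events over the 3 libraries were compared on a log2 scale of CPM (events per 1000000 events of a library) with 0.5 event added. Chromosome Y was left out of the tables of chromosomes. For cluster sharing, a cluster counted as shared with an overlap of at least 1 base on the same strand. Chance was estimated from 100 placements of the other library's clusters on positions drawn from that library's own crosslinked positions, and from 20 placements for classes of cluster size. Clusters of the 3 libraries that overlapped were merged into regions, and coordinates are 1-based in hg19.

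No hg19 genome or annotation was used here, so crosslinks were not joined to genes, transcript regions or sequence motifs. Tests planned on those, of untranslated against coding regions, of crosslinks against RNA level and of trinucleotides, were not run. The substitutes written with the plan were used: shares per chromosome, 10 kb bins, cluster sharing and FPKM of gene lists. The named genes followed a rule fixed before the data were examined: MSI2, EIF3A, the 10 genes with the highest mean FPKM and, of each list, the 3 genes with the highest mean FPKM. The 8 regions with the highest CPM among those with clusters in all 3 libraries stood in for the 8 most crosslinked genes. Some genes that the rule takes are not reported here. Other genes are named where 5 or fewer members of a list fell below 1 FPKM, and as low examples of a list; these, with MSI1, GATA1, EEF1A1 and the globins outside the rule, were chosen after their values were seen.

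The 16 gene lists were fixed before the data were examined, and no gene was in more than 1 list. The median of the mean FPKM of a list was compared with 10000 random lists of the same size from 18900 protein-coding genes (two-sided, Benjamini-Hochberg over the lists, threshold 0.05). Biotypes came from a RefSeq table of assembly GRCh38.p14, used for names only. Of the 25270 symbols, 22374 matched it directly, 1700 through a synonym with 1 meaning, and 1196 did not match. An FPKM of 0 can be a failed estimate, since genes that every cell uses were also at 0, so genes are described as listed at 0 with the value of each library.

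Tests on simulated data were run first. When 50% of library 3 clusters were copied into a made-up library and the rest placed at random, 55.7% were measured as overlapped against 55.6% expected, over 39962 clusters. The expected share was computed from the same placed clusters, so this checks the counting of overlaps and not the estimate of chance. With no copied cluster, the share was 1.01 times that of random placement, where both used the same placement rule. Of 200 random lists of 13 among 18000 simulated genes, 4.0% passed 0.05, and 93.5% of 200 lists of 40 genes raised 4-fold were recovered. No shorter raised list and no lowered list was simulated. The share recovered therefore does not cover the lists of 8 to 13 genes that did not pass below. For 1-event clusters, the check on events around them without the flank was first held to the bound of 1.5 set for the whole window, which library 1 did not clear by its bootstrap interval, and then, after its value was seen, to the 1 or less that the explanation needs. Alternatives tried were other overlaps, scores and placements for clusters, other bins and depths for correlations, other backgrounds for gene lists, and each library left out in turn. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used.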

Results

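The study concerned the RNAs bound by Musashi 2 (MSI2), an RNA-binding protein of stem cells and leukaemias, and their translation in K562. K562 is a chronic myeloid leukaemia line that carries the BCR-ABL fusion and makes embryonic and fetal globins. The series had 18 samples, and 6 of them were analysed here: 3 iCLIP libraries and 3 RNA-seq libraries of cells with a FLAG-MSI2 transgene. The other 12 samples, total and polysomal RNA of cells with a control shRNA or an MSI2 shRNA in 3 replicates each, were not analysed here, so neither knockdown nor polysome loading is described. In iCLIP, ultraviolet light links a protein to the RNA it touches, and the start of each truncated cDNA marks the crosslinked base. Each such cDNA is called a crosslink event below, and CPM stands for events per 1000000 events of a library. Library 1 held 6521636 events at 4764111 positions, library 2 held 2352989 at 1933474, and library 3 held 1546901 at 1267966. A position had 1 event in 85.9% ± 3.21 (SD, n = 3) of cases. No control iCLIP library was analysed, so every value below is a level in FLAG-MSI2 libraries and not an enrichment over background. The labels did not say whether replicates came from separate cultures, so the SDs measure the spread between libraries, which can be technical.

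The pair of shared regions with the most crosslink events lay on chromosome 11. The regions ranked here had a low-FDR cluster, that is a group of significantly crosslinked positions called by the authors, in all 3 libraries, and the 8 with the highest CPM are given in hg19 coordinates, with CPM summed over the region and so not corrected for width. Of these, 3 lay side by side on the plus strand of chromosome 11. The region at 65266514 to 65269806 held 4040 ± 708 CPM (SD, n = 3), the highest value. Its neighbour at 65270949 to 65271710 held 2231 ± 623, and the next, at 65271720 to 65272832, held 1561 ± 197. The stretch from 65264501 to 65273500 held 0.911% ± 0.159 of all events (SD, n = 3). A stretch of 76 bases on the plus strand of chromosome 6, at 52860642 to 52860717, held 1852 ± 463 CPM. Mitochondrial RNA gave 1070 ± 335 CPM at bases 3059 to 3214 of the plus strand. The remaining regions were on the plus strand of chromosome X at 77381524 to 77381741 with 749 ± 320 CPM, on the minus strand of chromosome 7 at 135611811 to 135613069 with 743 ± 143, and on the minus strand of chromosome 4 at 174252874 to 174253173 with 631 ± 204. No annotation of hg19 was used here, so these positions were not assigned to genes, exons or untranslated regions. Their CPM was lowest in library 1 in all 8 regions.

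**Figure D1:**
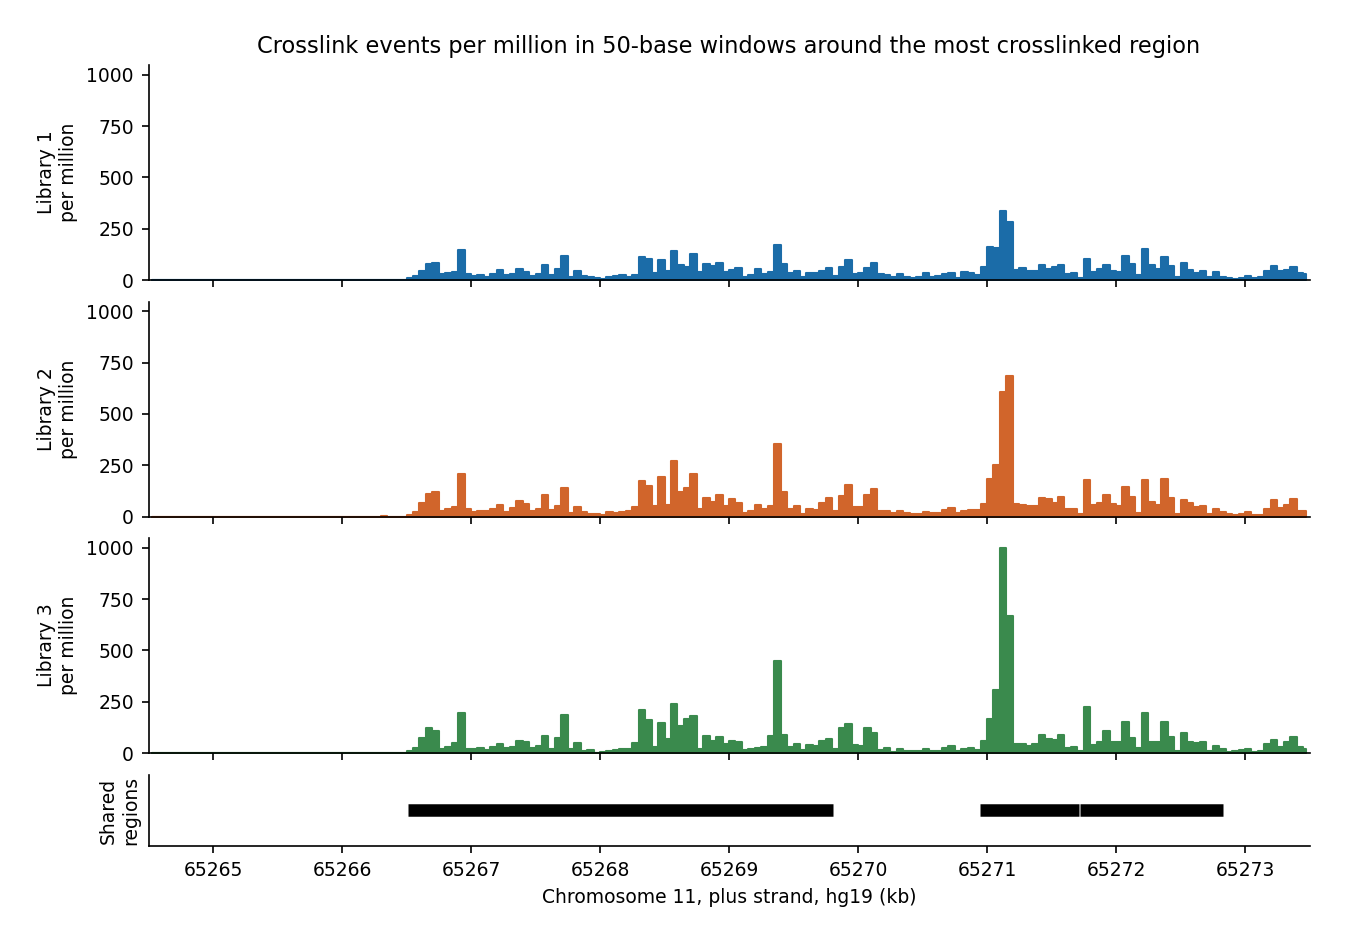
Crosslink events in CPM (y axis) in 50-base windows along the plus strand of chromosome 11 in hg19 (x axis, kb), with 1 panel per FLAG-MSI2 iCLIP library; black bars mark the 3 regions of this stretch with clusters in all libraries. The window that starts at 65271101, the highest in libraries 1 and 3, reached 336 CPM in library 1, 605 in library 2 and 997 in library 3; the next window, at 65271151, was the highest in library 2, with 684 CPM.

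Events were spread over the genome in nearly the same proportions in all 3 libraries. Chromosome 1 held the largest share, 12.5% ± 0.0510 of events (SD, n = 3). Chromosomes 6, 2, 3, 7 and 5 followed with 7.10% ± 0.0522, 7.09% ± 0.0785, 6.80% ± 0.0280, 6.59% ± 0.00473 and 6.44% ± 0.0593. Mitochondrial RNA took 0.683% ± 0.0841, with 0.592% in library 1 (95% Wilson interval 0.586 to 0.598%), 0.758% in library 2 (0.747 to 0.770%) and 0.698% in library 3 (0.685 to 0.712%). This share was 0.190% ± 0.0392 with each crosslinked position counted 1 time and 1.30% ± 0.318 of the events inside clusters. Within it, 86.4% ± 1.04 of events were on the plus strand and 63.8% ± 1.49 lay inside clusters. Within 10 kb bins of at least 100 events, the strand with fewer events held 1.80% ± 0.181 of them, and 84.2% ± 1.08 of bins had under 1% on that strand. The 100 bins with the most events, taken in each library, held 8.62% ± 0.946 of its events, and the top 1000 held 28.3% ± 1.92. These intervals cover counting error only.

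The bins with the most events were on mitochondrial RNA and chromosomes 11, 6, 12 and 10. The first 10000 bases of the mitochondrial plus strand held 5303 ± 793 CPM (SD, n = 3). On the minus strand of chromosome 12, the bin from 24960001 to 24970000 held 1858 ± 482. The bin from 102120001 to 102130000 on the plus strand of chromosome 10 held 1571 ± 134. Across 71420 bins with at least 10 events in all, the log2 CPM of libraries 1 and 2 correlated with a Pearson r of 0.926 and a Spearman rho of 0.923. The r was 0.899 for libraries 1 and 3 and 0.870 for libraries 2 and 3, with a rho of 0.892 and 0.869. Libraries drawn at the same depths from the pooled rate of each bin, with counting noise as the sole difference, gave 0.934, 0.915 and 0.885 for these pairs. These lay above each observed value. The pooled rates carry counting noise of their own, which can raise the simulated values. The gap therefore does not show a difference between libraries beyond counting noise. The correlations are across bins, which are not independent replicates, and no p-value is given.

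FLAG-MSI2 clusters recurred between libraries more often than random placement gave. Library 1 had 150804 clusters, library 2 had 56465 and library 3 had 39962, with median widths of 15, 14 and 14 bases. Of library 3 clusters, 75.5% (95% Wilson interval 75.0 to 75.9%) were overlapped on the same strand in library 1 and 52.6% (52.1 to 53.1%) in library 2. Of library 2 clusters, 71.2% were overlapped in library 1 and 36.5% in library 3. Of library 1 clusters, which were the most numerous, 24.2% were overlapped in library 2 and 17.9% in library 3. Random placement of the other library's clusters on its own crosslinked positions gave 28.4% and 16.2% for library 3, 25.9% and 12.2% for library 2, and 8.93% and 7.35% for library 1, in the same order. The observed shares were 2.43 to 3.24 times those of random placement. Each of the 6 shares exceeded all 100 placements, with a one-sided permutation p of 0.0099, the smallest that 100 placements can give, and the same value after Benjamini-Hochberg adjustment over the 6. Clusters were called by the authors in each library at its own depth, so the shares also follow the number of clusters. This placement gave every crosslinked position the same weight, while clusters are called where events are dense. The low p can therefore follow from dense stretches that the libraries share, and does not by itself show recurrence beyond them. With placement weighted by events the shares were 2.20 to 2.83 times chance. They were 4.19 to 5.64 times chance with clusters moved by 100 to 500 bases.

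Recurrence rose with the number of events in a cluster, from 2 events upwards in every pair of libraries. Of library 1 clusters with over 50 events, 95.8% were overlapped in library 2, against 50.6% by random placement. For clusters of 6 to 10 events the share was 18.6%, against 5.30%. For those of 1 event it was 1.83% (95% Wilson interval 1.61 to 2.08%), against 1.52%. Library 1 clusters of 1 event were overlapped in library 3 in 1.02% of cases (0.863 to 1.21%), against 1.09%, so no excess was detectable there. In the other direction, library 3 clusters were overlapped in library 1 in 54.8% of cases at 1 event, in 43.1% at 2 events and in 99.9% at over 50 events, against 11.6%, 8.64% and 85.3% by random placement.

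**Figure D2:**
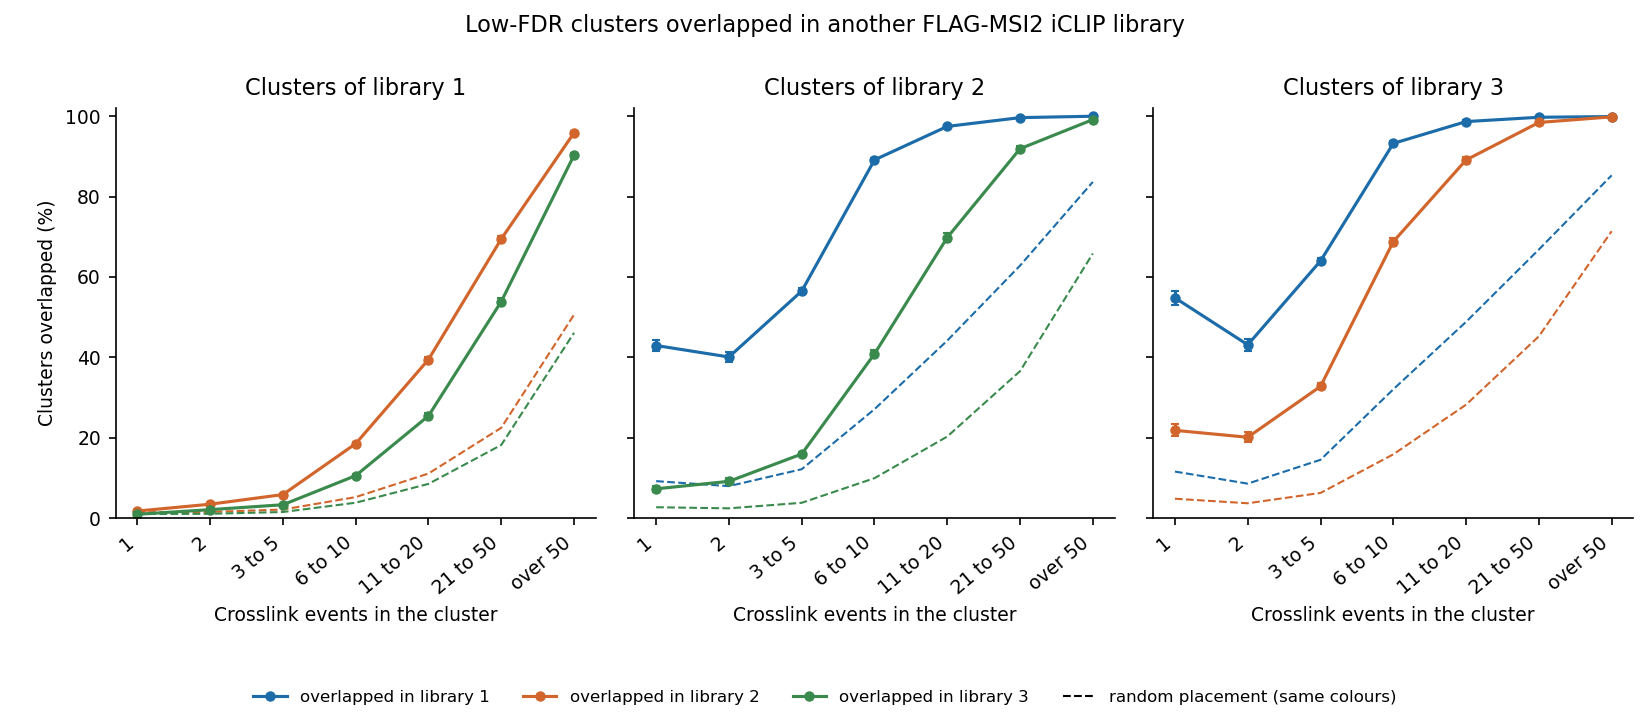
Share of low-FDR clusters overlapped by at least 1 base in another FLAG-MSI2 iCLIP library (y axis, percent) by the number of crosslink events in the cluster (x axis), with 1 panel for the clusters of each library; error bars are 95% Wilson intervals and dashed lines show the mean of 20 random placements. Library 1 clusters go from 1.83% at 1 event to 95.8% at over 50 events in library 2.

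Merging the clusters of the 3 libraries gave 175363 regions. Of these, 19724 had a cluster in all 3 libraries, 23828 in a pair of libraries and 131811 in 1 library. The regions common to all 3 libraries held 27.4% ± 3.52 of all events (SD, n = 3), and those of 1 library held 7.40% ± 2.36. Chromosome 1 had 2621 of the common regions (13.3%), chromosome 7 had 1399 and chromosome 2 had 1395. They fell into 8999 bins of 10 kb on 1 strand, and 947 bins with at least 5 regions held 37.2% of them. The densest bin had 36.

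MSI2 was among the abundant messages of these cells. Its level was 165 FPKM in library A, 140 in library B and 150 in library C, a mean of 152 ± 12.8 FPKM (SD, n = 3), above 97.3% of the 18900 protein-coding genes of the table. The letters name the 3 RNA-seq columns, which carry no replicate number. Transgene and endogenous MSI2 RNA were not told apart, and no library without the transgene was analysed. MSI1, the paralog of MSI2, was listed at 0 in library A, at 0.0255 FPKM in library B and at 0.0189 in library C. The highest mean was that of HBE1, the embryonic beta-like globin, with 12639 ± 1109 FPKM. Next came the ribosomal protein genes RPS18 with 5744 ± 92.7 and RPL11 with 4235 ± 249. RPS24 had 3787 ± 313 and RPL38 had 2826 ± 156. FTL, the light chain of the iron store ferritin, had 3450 ± 378, and SNORD36A, a small nucleolar RNA, had 3152 ± 277. The fetal globin genes HBG2 and HBG1 were also among the 10 genes with the highest mean. HBG2 was listed at 5268 FPKM in library A, 0 in library B and 7144 in library C, and HBG1 at 3975, 0 and 5327. HBG1 and HBG2 are nearly identical in sequence, so the split of reads between them is uncertain.

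**Figure D3:**
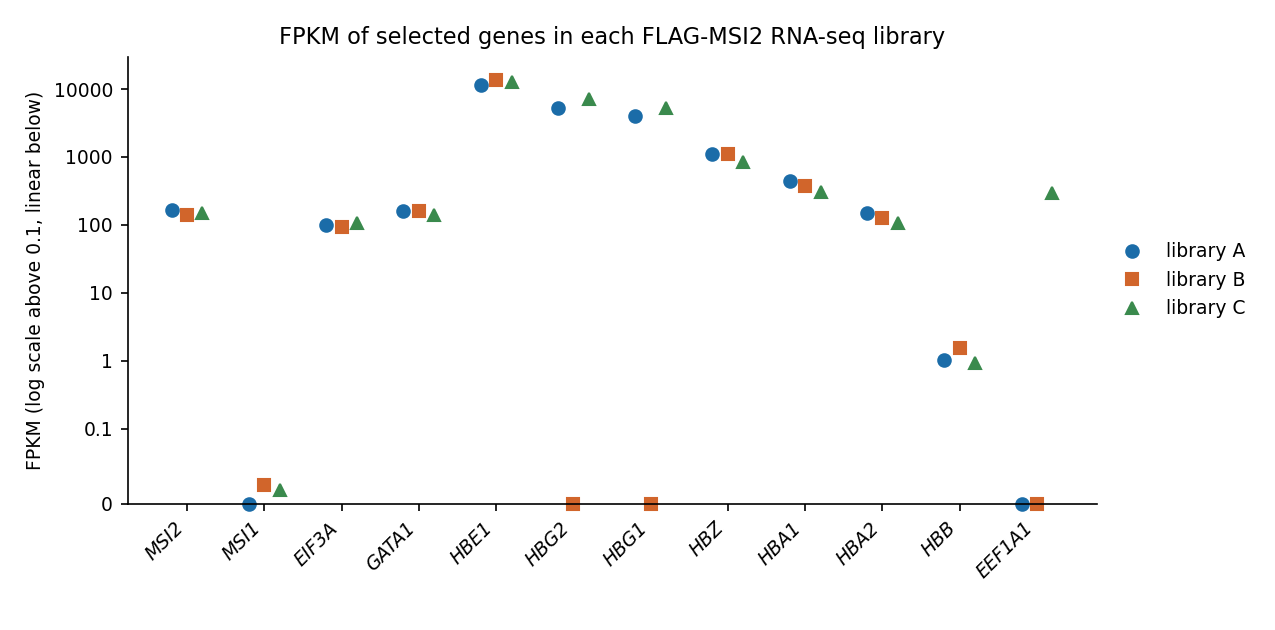
FPKM (y axis, log scale above 0.1 and linear below) of MSI2, MSI1, EIF3A, the erythroid regulator GATA1, 7 globin genes and EEF1A1 (x axis) in each of the 3 FLAG-MSI2 RNA-seq libraries, with 1 symbol per library. MSI2 lies between 140 and 165 FPKM, HBG1 and HBG2 are listed at 0 in library B, and EEF1A1 is listed at 0 in libraries A and B.

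The translation machinery was expressed at high levels. Of the 13 genes of eIF3, the initiation factor complex that binds the small ribosomal subunit, 12 had a mean of at least 1 FPKM, and the list median was 211 ± 2.82 FPKM (mean and SD of the 3 library medians, as for all lists below). EIF3K had 566 ± 22.1 FPKM (SD, n = 3, as for all genes below), EIF3I 443 ± 9.72, EIF3M 370 ± 15.3 and EIF3A, the largest subunit, 99.4 ± 7.48. EIF3C was listed at 0.00269, 0.00221 and 0 FPKM in libraries A, B and C. All 24 other initiation factors were at 1 FPKM or more, with a median of 80.1 ± 3.86. PABPC1, the cytoplasmic poly(A)-binding protein, had 505 ± 33.6, EIF1 366 ± 25.2 and the helicase EIF4A1 362 ± 15.8. The 10 elongation and release factors had a median of 124 ± 6.78, with EEF2 at 687 ± 96.9, EEF1G at 456 ± 20.7 and EIF5A at 264 ± 28.9. EEF1A1, the main elongation factor gene, was listed at 0 in libraries A and B and at 294 FPKM in library C. Of 78 cytosolic ribosomal protein genes, 75 were at 1 FPKM or more and the median was 660 ± 54.3. RPL21 had 0.283 ± 0.181 and RPL7 0.193 ± 0.0754.

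Genes of protein turnover, respiration, the cell cycle and RNA processing were also expressed throughout. The 31 proteasome genes were all at 1 FPKM or more, with a median of 163 ± 0.959. PSMB1 had 618 ± 10.4, PSMA4 341 ± 9.48 and PSMA1 338 ± 14.1. The 46 nuclear genes of the respiratory chain had a median of 163 ± 7.57, with COX7C at 1340 ± 82.2, ATP5B at 1169 ± 53.8 and UQCRH at 1147 ± 50.5. The 40 cell cycle genes had a median of 61.9 ± 3.07. PCNA, the sliding clamp of replication, had 358 ± 3.54, the helicase subunit MCM7 282 ± 9.35 and the kinase CDK1 216 ± 17.2. Of 55 RNA-binding and splicing factors, 54 were at 1 FPKM or more, the exception being MSI1, and the median was 101 ± 0.722. HNRNPA2B1 had 651 ± 6.48, HNRNPH1 332 ± 10.8 and HNRNPD 295 ± 5.20. The 17 cholesterol synthesis genes, all at 1 FPKM or more, had a median of 61.2 ± 2.60, led by INSIG1 with 298 ± 18.4, FDPS with 264 ± 24.6 and FDFT1 with 250.0 ± 30.7.

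Erythroid genes were high and markers of other blood cells mostly low. Of 26 erythroid genes, 25 were at 1 FPKM or more, with a median of 170.3 ± 24.6, from 177 in library A, 143 in library B and 191 in library C. HBG1 and HBG2 enter the library B median at 0 and lower it. Over 23 other erythroid genes the median log2 ratio of library B to the mean of A and C was 0.0124 (bootstrap interval -0.0354 to 0.0549). HBE1, HBG2 and HBG1 led the list with the values above. BCL11A, a repressor of fetal globin, was listed at 0 in all 3 libraries. Of 23 genes of BCR-ABL signalling, 22 were at 1 FPKM or more, with a median of 42.3 ± 1.35. PIM1 had 368 ± 48.9 and the adaptor CRKL 245 ± 11.96. Of 8 myeloid markers, 3 were at 1 FPKM or more, namely LYZ with 33.6 ± 0.971, CD68 with 8.33 ± 0.362 and SPI1 with 6.52 ± 1.38. The sole lymphoid marker of 8 at this level was CD3D with 27.4 ± 2.33, while NKG7 had 0.325 ± 0.135. Of 10 epithelial and fibroblast markers, 5 were at 1 FPKM or more. KRT18 had 164 ± 5.40, KRT8 108 ± 10.3 and VIM 99.9 ± 8.10, while the collagen gene COL1A1 had 0.284 ± 0.0705.

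Genes reported as Musashi targets covered a wide range. Of 13 such genes, 9 were at 1 FPKM or more, and the list median was 10.6 ± 1.48. The chaperone gene HSP90AA1 had 974 ± 99.2, the GTPase gene CDC42 102.2 ± 4.06 and MYC 70.2 ± 3.09. IKZF2 with 0.172 ± 0.0106, JAG1 with 0.0829 ± 0.0202, HOXA9 and CYP1B1 were below 1 FPKM, and in libraries A, B and C HOXA9 was listed at 0.0114, 0.0189 and 0 FPKM and CYP1B1 at 0.00433, 0.00357 and 0. Of 22 replication-dependent histone genes, 19 were at 1 FPKM or more, with a median of 22.5 ± 4.01. HIST1H1C had 895 ± 139, HIST1H2BK 698 ± 44.1 and HIST1H2BJ 114 ± 15.5, against 0.180 ± 0.0931 for HIST1H3A. Values of histone genes can depend on whether RNA was selected by its poly(A) tail, which is not stated here. A low value is therefore not read as low expression.

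**Figure D4:**
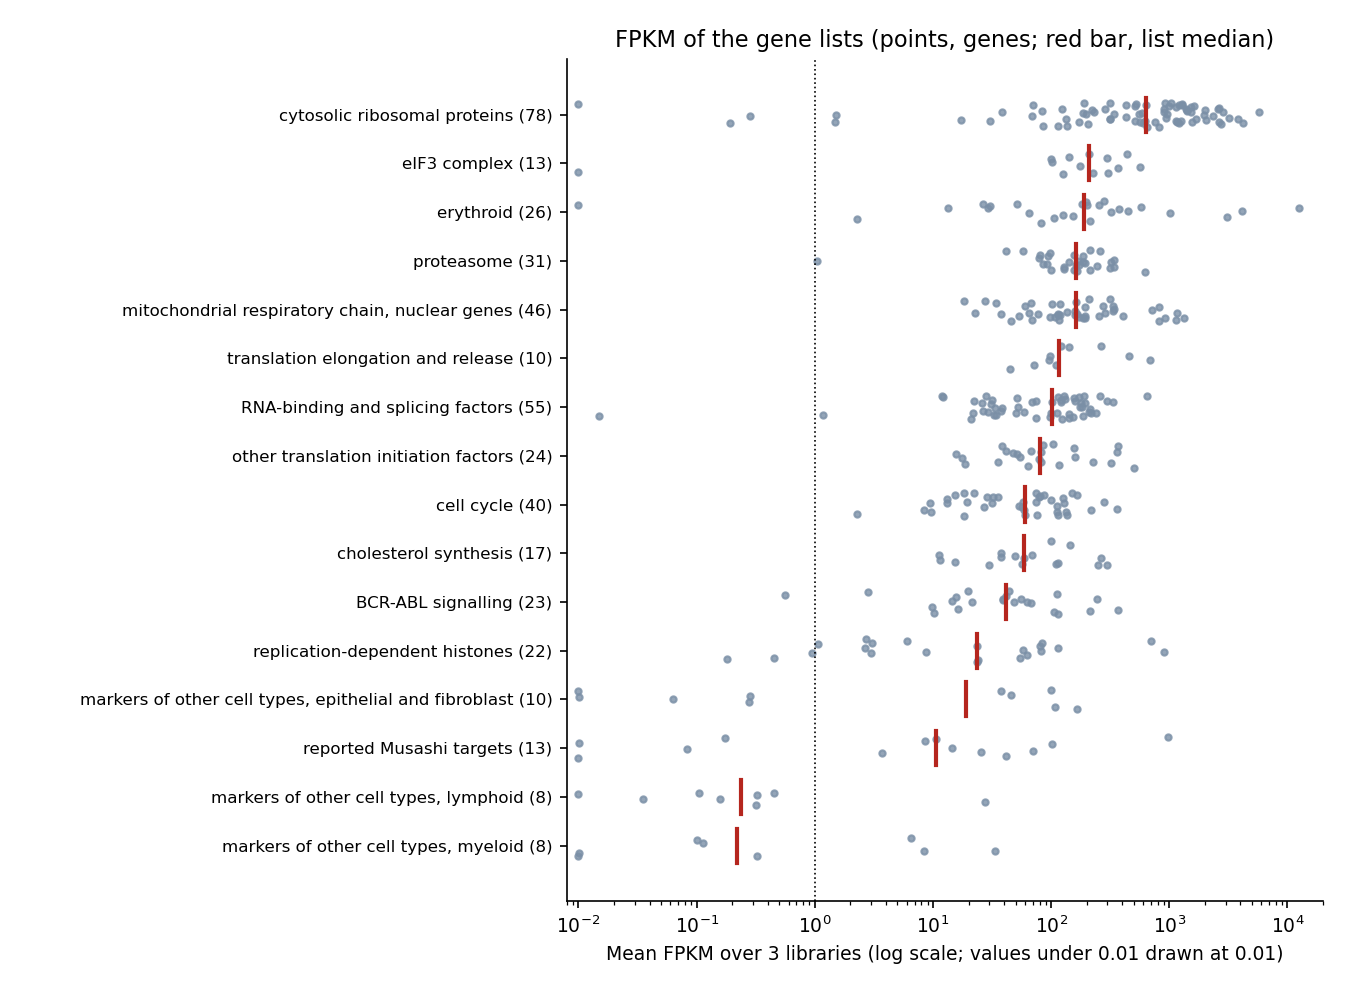
Mean FPKM over 3 FLAG-MSI2 RNA-seq libraries (x axis, log scale, values under 0.01 drawn at 0.01) of the genes of 16 lists (y axis, number of genes in brackets); each point is a gene, red bars are medians of these means and the dotted line marks 1 FPKM. Ribosomal protein genes have the highest list median and the myeloid and lymphoid markers the lowest.

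Against 10000 random lists of as many protein-coding genes, 12 of the 16 lists had a higher median FPKM and 0 a lower one after Benjamini-Hochberg adjustment over the 16, but the calls depended on the background. The other 4 lists did not pass: the reported Musashi targets (two-sided permutation p adjusted to 0.188), the myeloid and the lymphoid markers (0.384 each) and the epithelial and fibroblast markers (0.0551). Of the 12, all but the histones had an adjusted p of 0.000291, from the smallest p that 10000 lists can give (0.0002), and the histone list had 0.00133. Of these, 11 also passed against protein-coding genes at 1 FPKM or more. The histones did not, with an adjusted p of 0.165, and the myeloid and the lymphoid markers were lower than random lists of such genes (adjusted p of 0.000291 each). The test compares these lists with other genes in FLAG-MSI2 cells and compares no conditions. Several of the 12, such as the ribosomal, proteasome and respiratory chain lists, hold genes that every cell uses. Their high rank among all protein-coding genes could be foreseen and says nothing particular to these cells.

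The RNA-seq libraries agreed closely for protein-coding genes with no value of 0, and less over all genes. Across 10205 of them with a mean of at least 1 FPKM and no value of 0, log2 FPKM with a pseudocount of 0.1 correlated with a Pearson r of 0.996 for libraries A and B, 0.994 for A and C and 0.994 for B and C, across genes, which are not independent replicates. Over all 11359 genes with a mean of at least 1 FPKM, non-coding genes and values of 0 included, the r was 0.911, 0.924 and 0.920 for these pairs. The coefficient of variation of the 6150 protein-coding genes with no value of 0 and a mean of at least 10 FPKM had a median of 5.81%. On average 11237 ± 95.1 genes (SD, n = 3) of the 25270 in the table were at 1 FPKM or more.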

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

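For the large clusters and the RNA-seq values of 0, the tests on windows with over 200 events and all those on HBG1, HBG2 and EEF1A1 were chosen after the results were seen; the other tests were set before. The design names no group that differs between these libraries, so no biological explanation was tested for the iCLIP patterns.

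Crosslink events on unplaced or unlocalised contigs of hg19 stood outside the chromosome comparison and lay above the 3 counts that a count of 0 allows. There were 13375 such events in library 1, 5004 in library 2 and 3133 in library 3, or 0.207% ± 0.00527 of events (SD, n = 3).

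The shallower libraries held more CPM (events per 1000000 events of a library) than library 1 in 9 of the 10 bins of 10 kb with the most crosslinks; in the other, on the plus strand of chromosome 19 from 29100001, library 1 was the highest, with 1547 CPM against 1420 and 1444. In 100-base windows where no position held over 20% of the library 3 events, the ratio of library 1 to library 2, each in CPM, was 1.01 at 6 to 10 library 3 events, 0.929 at 50 to 200 and 0.743 (bootstrap interval 0.710 to 0.782) above 200. More diffuse background in library 1 may lower this ratio at moderate density, where windows of 20 to 50 events had 0.962 times the ratio of all windows with 1 or 2 events (0.956 to 0.969), between the values set for and against this cause. As the cause above 200 events, a diffuse background is argued against, since the ratio fell further, to 0.7999 times that at 50 to 200 (0.764 to 0.842). A limit on counts per position from the number of random barcodes stays open: windows dominated by 1 position gave 0.705 times the ratio of spread windows (0.558 to 0.928), but only 7 such windows existed.

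Clusters of 1 event in library 1, the deepest library, were seldom overlapped in the other libraries. From a shallower to a deeper library the share was higher. Those of library 3 were overlapped in library 1 in 54.8% of cases, against 11.6% by random placement, and in library 2 in 21.9%, against 4.89%. The part of depth in this was not tested. In library 1, the median number of events within 500 bases was 22 around 1-event clusters and 13 around 1-event positions outside clusters. The ratio with 1 added to each was 1.64 (bootstrap interval 1.61 to 1.71). Isolated events in sparse regions, as the source, need 1 or less. Without the 15 bases on either side on which clusters were called, a check added after the values were seen, it was 1.54 (1.46 to 1.54). In libraries 2 and 3 it was 2.14 (2.00 to 2.29) and 2.80 (2.60 to 3.00). This test does not decide on isolated events. Through the calling, all 1-event clusters had another event within 15 bases, against 47.2% of the outside positions of library 1. Positions of library 1 had another at 20 bases in 11.6% of cases and at 500 bases in 5.96%, so density reached past the flank. A ratio above 1 can thus follow from the calling. Whether neighbours within the flank of 15 bases raised these positions past the threshold stays open, since the calling itself, which used this flank, fixes the 100% of 1-event clusters that had another event that near. Whether the positions are better supported than other single events stays open in library 1, where an event at the same position in library 2 or 3 was 1.27 times as frequent (1.19 to 1.35). In libraries 2 and 3 it was 1.77 and 1.81 times as frequent.

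HBG1 and HBG2 were listed at 0 in library B, and EEF1A1 in libraries A and B, beside high values elsewhere. A loss of the erythroid programme in library B is argued against: over 23 other erythroid genes the median log2 ratio of library B to the mean of A and C was 0.0124 (bootstrap interval -0.0354 to 0.0549). Reads counted on another globin gene are argued against as well, since 8 other globin genes together exceeded libraries A and C by 16.01% of the HBG1 and HBG2 sum (22.9% against A, 10.9% against C). Values that the quantification did not return may be the cause and stay open: besides EEF1A1, 2 of 155 translation and proteasome genes were listed at 0 in at least 1 library. Among protein-coding genes with at least 10 FPKM in some library, HBG1, HBG2 and EEF1A1 were the sole ones at 0 in another. If low small RNA values stood for equal read counts, library B was the deepest and C the shallowest. Their most common FPKM ratios were 1.21 (A to B), 0.829 (A to C) and 0.683 (B to C). The values of 0 then fell in the deeper libraries, though HBE1, with the highest mean, had 13709 FPKM in library B. Whether depth played a part was not tested.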

How the results depend on the processing

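The alternatives for bins of 1 kb and without the top bins, for weighted or shifted placement, for clusters of over 1 event and for gene lists were chosen after seeing the data. All 36 alternative values of cluster sharing stayed above chance past the threshold, at 2.20 to 8.99 times chance; an overlap of at least 50% of both clusters lowered the shares to between 7.002 and 29.1%. The regions common to all 3 libraries numbered 13592 to 18431. The mitochondrial share moved to 0.190% with each position counted 1 time and to 1.30% inside clusters, and that of chromosome 1 to 12.3% and 13.5%. Without the minimum of events r was 0.868 (libraries 1 and 2), 0.859 (1 and 3) and 0.860 (2 and 3), and rho 0.742, 0.737 and 0.724. Thinned to the shallowest library, r was 0.885, 0.876 and 0.875 for these pairs, closer together than at full depth. In 1 kb bins r was 0.809, 0.770 and 0.705 for libraries 1 and 2, 1 and 3, and 2 and 3, and rho fell further, to 0.673, 0.625 and 0.590. The cause of these moves was not tested. The count of lists above random lists was 11 to 13. Of 96 alternatives for list medians, 91 kept their side of the threshold. Against genes at 1 FPKM or more the histones lost it, and the myeloid and lymphoid markers were below random lists (adjusted permutation p = 0.000291). Epithelial and fibroblast markers passed against all genes (0.0197) and without genes listed at 0 (0.00591). Leaving out 1 of 3 libraries cannot move a mean beyond 1 SD, so it says nothing of stability there. No paired analysis was possible because the RNA-seq columns carry no replicate numbers and crosslinks were not joined to genes. Without an hg19 annotation or genome, the order of coding and untranslated regions and all alternatives for region densities, crosslinks over RNA, gene-list crosslinks and trinucleotides were not run.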

Other observations

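The globin genes of these cells differed by orders of magnitude. Besides HBE1, the embryonic alpha-like globin gene HBZ had 1010 ± 153 FPKM (SD, n = 3), HBA1 375 ± 73.2 and HBA2 127 ± 21.1. The adult beta globin gene HBB had 1.16 ± 0.332. GATA1, a regulator of erythroid genes, had 153 ± 11.95. HBA1 and HBA2 share most of their sequence, so their split is uncertain. These genes, and those named next, were chosen after their values were seen.

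Among histone genes, the 3 with the highest mean FPKM were HIST1H1C, HIST1H2BK and HIST1H2BJ, and several others were far lower, such as HIST1H4C with 2.71 ± 0.478 FPKM and HIST1H1B with 0.454 ± 0.124. As said above, such low values can depend on whether RNA was selected by its poly(A) tail. Of the epithelial markers, the keratin gene KRT19 had 46.0 ± 6.51 and EPCAM 38.0 ± 0.224, while CDH1 was at 0.0101 ± 0.00666. Of the T cell markers, CD3E had 0.318 ± 0.150, against 27.4 ± 2.33 for CD3D.

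In mitochondrial RNA, 71.4% ± 4.35 of events (SD, n = 3) lay on the plus strand within its first 3300 bases, a window set after the data were seen. Crosslinked positions of 1 library recurred at the same base in another 1.16 ± 0.0117 times as often as at a distance of 1 base, 1.28 ± 0.0216 times as often as at 2 bases, 1.85 ± 0.0754 times as often as at 20 bases and 4.01 ± 0.421 times as often as at 500 bases (SD over the 3 pairs of libraries).

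With 136 genes listed at 0 in 1 or 2 RNA-seq libraries and at 10 FPKM or more in another, 133 were small RNA genes. The number of other events at the position of an event, per 1000000 events of the library, was 0.388 in library 1, 0.784 in library 2 and 1.047 in library 3.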
